A study of Mus musculus with 22 samples.

How the data were processed

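Gene expression was measured on Affymetrix mouse gene ST 1.0 arrays in the cortex and hippocampus of 6 Ts1Cje and 5 WT female littermates, 22 arrays from 11 animals. Per the labels' protocols, Ts1Cje males had been backcrossed to C57Bl/6J, RNA came from frozen dissected tissue with an integrity number above 9, and a different extraction kit was used for each region. Per the submitters' processing notes the arrays were processed with RMA, a method that corrects the background, normalizes arrays and summarizes probes. The deposited values are log2 signals, with 1 value per array for each of 21225 features identified by Entrez gene number. The versions of RMA and of the probe definition, the background settings and whether both regions were normalized together are not given in the sources used here. The array medians differed between regions, at 7.53 to 7.62 in cortex and 6.91 to 6.95 in hippocampus, so genotype was compared within a region and the region difference was also computed after centring each array on its median. The number of arrays limits the precision.

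Features were named through the gene table of the RefSeq assembly GRCm38.p6, which was used only for names and for the order of genes along chromosomes. Of the 21225 features 20239 carried 1 gene symbol, matched that table and were tested, 986 carried none, and 0 carried several. No symbol was held by more than 1 feature, and 0 symbols were updated through the table. No filter was applied to dim genes. The title of 2 arrays gives WT animal 60 where their description gives 61, and the number in the title was used.

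Fits were made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior, two-sided, Benjamini-Hochberg adjustment over all 20239 genes, called at adjusted p under 0.05). Genotype was compared in the 11 cortex arrays, in the 11 hippocampus arrays, and in the 11 means of each animal's arrays. The difference of the genotype effect between regions and the difference between regions were fitted on all 22 arrays in 4 groups. The overlap of the regional calls was set beside the count expected from the sizes of both sets of calls. The comparisons, the 37 gene lists (16 of them cell type or tissue markers), the rule for naming genes and all alternatives but 1 were chosen before the data were examined. Of the 950 list genes sought 879 were measured.

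Lists were tested with camera of limma, which compares the members with the other genes, with an inter-gene correlation preset at 0.01 and, as an alternative, estimated from the data. P values were adjusted over the 37 lists within each comparison. The mean of each list per animal was also compared with an exact two-sided permutation test over the 462 splits of 11 animals into 5 and 6, for which the smallest possible p is 0.00216. Members of a list were adjusted both over all genes and over the list alone.

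Genes were named by a rule. In each genotype comparison the rule took up to 8 called members of the triplicated segment with the largest log2 fold change, and the 4 lowest members brighter than the median gene. Outside the segment it took up to 12 called genes with the largest absolute log2 fold change or, where fewer than 5 passed, those that passed and those with the lowest p up to 5. From each other list it took up to 4 members past the threshold adjusted over the list alone. Sod1 and all measured genes of distal chromosome 12 were always included. For the difference between the regions' genotype effects it took the 10 largest called genes or the 5 with the lowest p. For the regions it took the 5 highest on each side and up to 3 markers from each of the lists of regional neurons. Genes named outside this rule, Tiam1 among them, were picked after their values were seen.

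Pairing comes from the labels, which give the same animal number for a cortex and a hippocampus array. After the group means were removed, the arrays of an animal correlated across genes at a median r of 0.265 (0.052 to 0.761), and the animal's own partner was the best match for 2 of 11 animals. A fit with the animal as a random replicate block gave a consensus correlation of 0.436. No pair of arrays held identical values (highest r within a region 0.998).

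The alternatives were limma with a trend and a robust prior, array weights, quantile normalization of all arrays, arrays centred on their median, the 6746 dimmest genes left out, every feature tested, an adjusted p under 0.1, a single fit on all 22 arrays, the animal as a random or fixed replicate block, the series of animal numbers as a covariate, adjustment over the genes outside the segment alone, and leaving out each animal in turn. Leaving out animals 60 and 64 together was added after seeing the data. Averaging several features of 1 gene did not apply, since no gene had more than 1. The counts were also computed for 100 splits of the animals, the real one included.

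The steps were tested on simulated data with the spread of each comparison, 20239 genes of which 200 were changed, 50 at each fold. Noise was drawn independently for each gene and array. Departures that genes or arrays share were left out, so the rates apply to such data alone. All 200 changed genes were tested together, and those at folds of 2 and 4 ease the adjustment for the smaller folds. The rates at 1.3 and 1.5 are therefore not the power in the real data. In the real cortex 0 of the 68 measured genes of the triplicated segment (median fold 1.3) were called over all genes. At folds of 1.3, 1.5, 2 and 4 the cortex fit recovered 26%, 42%, 80% and 100% of changed genes, with 6 false among 130 calls. The hippocampus fit recovered 42%, 74%, 92% and 100% (6 of 160 calls false), and the fit on the mean of both regions 42%, 80%, 92% and 100% (14 of 171). The fit of the difference between regions' effects recovered 14%, 52%, 64% and 100% (2 of 117), and the region fit 54%, 86%, 100% and 100% (10 of 180). In a simulated cortex a list of 41 genes shifted by a log2 of 0.2 was called, and 0 of the other lists. The simulated genes were independent, so this does not test the preset correlation where genes correlate.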

Results

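Expression was measured in the cortex and the hippocampus of 11 female mice aged 8 to 10 weeks, 6 Ts1Cje mice and 5 wild-type (WT) littermates. Ts1Cje is a mouse model of Down syndrome that carries an extra copy of distal chromosome 16 joined to chromosome 12. The list of segment genes, fixed beforehand, ran from the gene after Sod1 to Zbtb21, so Sod1 was counted outside the segment. The study asked which genes and pathways the extra segment affects and which of these are affected in both brain regions. Each animal gave 1 array per region, 22 arrays in all, and their number limits the precision. Values were log2 signals, and each genotype comparison set 6 Ts1Cje animals against 5 WT animals.

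The arrays of WT animal 60 and Ts1Cje animal 64 differed from the rest in both regions. Their log2 values spread less over the 21225 features. Their signals were raised among the dimmest 10% of genes, by 0.69 and 0.44 in cortex and by 0.23 and 0.31 in hippocampus. The 9 other arrays of each region correlated with their region at a median r across genes of 0.996 to 0.997 in cortex and 0.995 to 0.996 in hippocampus. Arrays 60 and 64 stood at 0.967 and 0.976 in cortex and at 0.991 and 0.985 in hippocampus. All 11 animals were kept in every comparison, and counts of genes and lists without these 2 animals, a setting chosen after seeing the data, are also given.

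**Figure D1:**
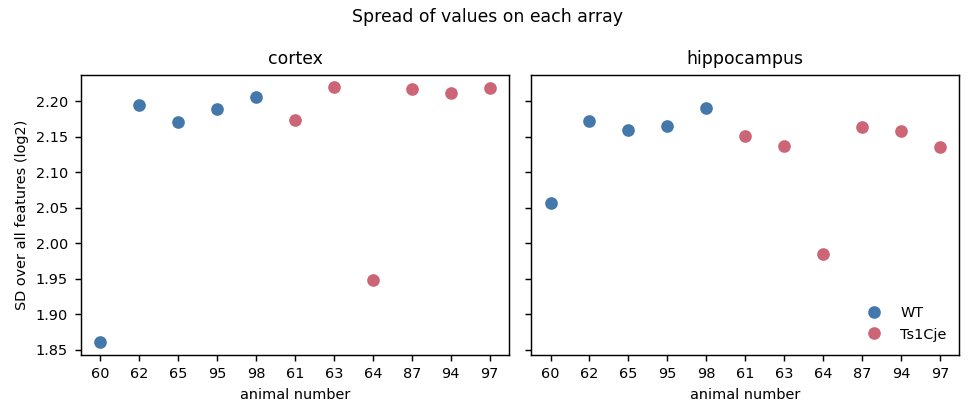
Standard deviation (log2) of the 21225 features on each array, by animal number and region, in blue for WT and red for Ts1Cje, with 1 point per array. Animals 60 and 64 lie at 1.86 and 1.95 in cortex and at 2.06 and 1.98 in hippocampus, below the other 9 arrays of each region.

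In cortex, Dnah11 (Entrez 13411), which encodes a dynein heavy chain of motile cilia, rose 7.34-fold in Ts1Cje. Its log2 signal went from 6.94 ± 0.348 (SD, n = 5) in WT to 9.82 ± 0.0706 (SD, n = 6) in Ts1Cje, and all 6 Ts1Cje animals lay above all 5 WT animals. The log2 fold change was 2.88 ± 0.136 (SE; limma adjusted p = 3.24e-06), and the call held when any single animal was left out. Dnah11 lies near the distal end of chromosome 12, the chromosome to which the extra segment is joined. Among its distal neighbours, Tmem196 (a transmembrane protein; Entrez 217951) and Itgb8 (integrin beta 8; Entrez 320910) had log2 fold changes of -0.67 ± 0.0851 and -0.81 ± 0.174 (SE). In each of these 2 genes all 6 Ts1Cje animals lay below all WT animals, and both missed the threshold over all genes with adjusted p of 0.0577 and 0.587. The transcription factor Sp4 (Entrez 20688) stood at -0.42 ± 0.138 (SE; adjusted p = 1). Among the 9 measured genes of distal chromosome 12, 1 was higher (Dnah11) and 3 were lower (Tmem196, Itgb8 and Sp4), adjusted over the list alone, with adjusted p of 1.44e-09, 2.57e-05, 0.00189 and 0.0258. Over all genes 1 of the 9 was called.

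The 68 measured genes of the triplicated segment had a median log2 fold change of 0.37 in cortex, a fold of 1.3, and 56 of them were above 0. Their quartiles ran from 0.13 to 0.47, below the log2 of 1.5 (0.585) that 3 copies against 2 would give in proportion. Whether the arrays report folds in proportion was not tested. As a group they rose (camera, a test of a gene list against the other genes, adjusted p = 2.04e-73; adjusted p = 1.16e-05 with an estimated correlation). The exact two-sided permutation p of the list mean was 0.00216, the smallest that the 462 splits of the animals can give. No member passed over all 20239 genes, and 43 passed adjusted over the list alone. Among those were Ets2, a transcription factor, at 0.56 ± 0.107, the cell adhesion gene Dscam at 0.48 ± 0.0979, and Synj1, a phosphatase of synaptic vesicle recycling, at 0.43 ± 0.0599 (SE). The interferon receptor genes Ifnar1, Ifnar2 and Ifngr2 stood at 0.48 ± 0.103, 0.59 ± 0.159 and 0.50 ± 0.0894 (SE). These 6 genes were picked after their values were seen. The lowest values among members brighter than the median gene were those of Olig2 (0.11), Pcp4 (0.13), Zbtb21 (0.18) and Hmgn1 (0.19), and of these only Pcp4 passed adjusted over the list alone (adjusted p = 0.0398). The value of Hmgn1 was 0.30 without animal 60 and 0.11 without animal 62.

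Over all genes limma called 1 gene in cortex, Dnah11, which lies outside the segment, and 263 genes had an unadjusted p under 0.05, against 1012 expected by chance and 1208 without animals 60 and 64. With all animals the p values thus ran higher than chance gives, so the single call does not show that other genes were unchanged. The next lowest p values outside the segment and distal chromosome 12 belonged to Cyb5r1 (Entrez 72017; 0.25 ± 0.0521) and Abca8a (Entrez 217258; 0.54 ± 0.111, SE), each with an adjusted p of 0.549. Sod1 (Entrez 20655), which encodes superoxide dismutase 1 and borders the segment, had a log2 fold change of 0.62 ± 0.155 (SE; adjusted p = 1), and 1 of 6 Ts1Cje animals lay above all WT animals. Single animals moved these counts: 2 genes were called without animal 60 and 7 without animal 64, with 2 outside the segment in each case. Without both, 32 genes were called, 30 higher and 2 lower, of which 27 lay in the segment. The 5 others included Tmem196 (adjusted p = 0.000578), Itgb8 (0.000152) and Sod1 (0.70; adjusted p = 0.000578).

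**Figure D2:**
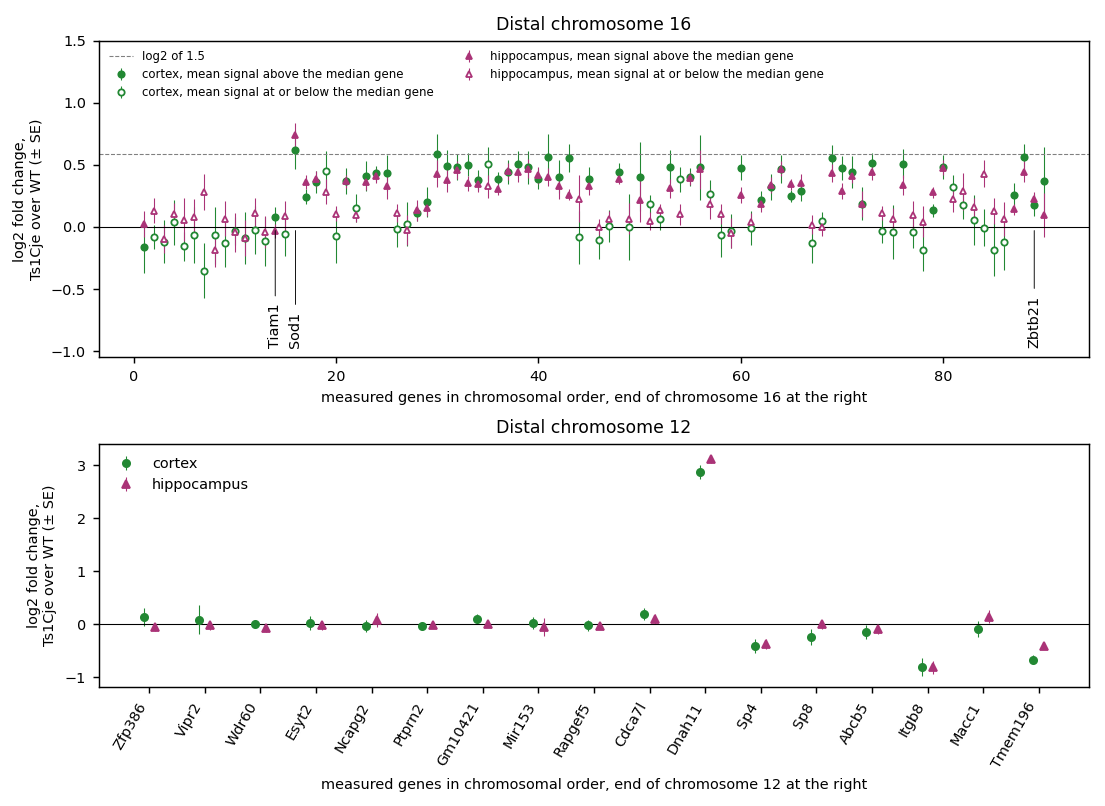
Log2 fold change of Ts1Cje over WT (± SE, 6 against 5 animals) for the measured genes of distal chromosomes 16 and 12 in chromosomal order. Circles mark cortex and triangles hippocampus. Markers for chromosome 16 are open where the mean signal is at or below the median gene, and those for chromosome 12 are all filled. On chromosome 16 the values step up from Tiam1 to Sod1 and stay mostly below the dashed log2 of 1.5, while on chromosome 12 Dnah11 stands at 2.88 and 3.12 and Tmem196 at -0.67 and -0.41.

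Gene lists fixed beforehand shifted by smaller amounts in cortex. The 41 interferon-stimulated genes, which cells switch on in response to interferon, were higher in Ts1Cje by a mean log2 of 0.185, with 35 of 41 above 0. The immediate early genes, which neurons switch on with activity, were higher by a mean of 0.217, with 25 of 30 above 0. Camera with its preset correlation called both, with adjusted p of 9.37e-14 and 1.89e-10, in every omission of a single animal. Neither call held with the correlation estimated from the data (adjusted p = 0.0856 and 0.526 with an estimated correlation). Without WT animal 98, whose immediate early mean was 8.97 against 8.26 to 8.63 in the other WT animals, the mean difference of that list was 0.328. Without animals 60 and 64 the preset calls held (6.63e-11 and 2.8e-06), and adjusted p = 0.462 and 0.686 with an estimated correlation. The exact two-sided permutation p, not adjusted over lists, was 0.0152 for the interferon-stimulated genes and 0.145 for the immediate early genes. No member of either list passed over all genes or adjusted over the list alone. The class I histocompatibility genes H2-K1 and H2-D1 stood at 0.65 ± 0.218 and 0.58 ± 0.179, and the activity genes Npas4 and Egr2 at 0.72 ± 0.253 and 0.63 ± 0.272 (SE), all 4 picked after their values were seen.

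**Figure D3:**
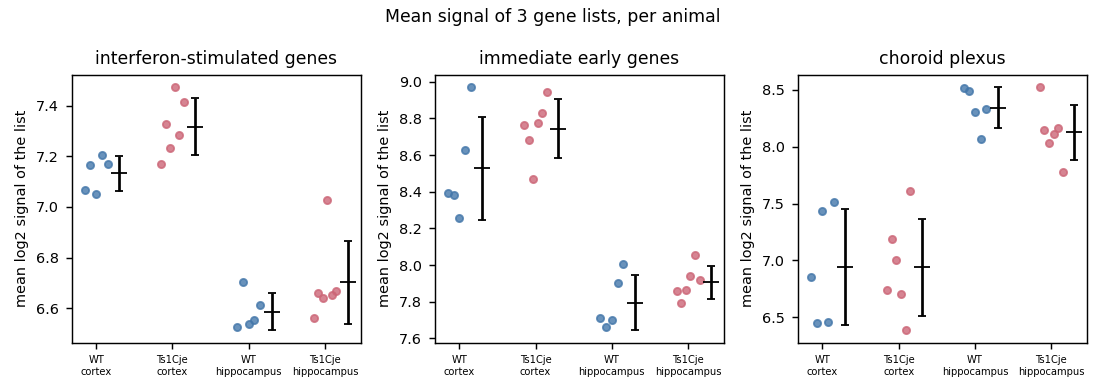
Mean log2 signal of 3 gene lists in each animal, by genotype and region, with a tick at the group mean and bars of 1 SD (5 WT and 6 Ts1Cje animals). In cortex the Ts1Cje animals tend to lie higher for interferon-stimulated genes (exact permutation p = 0.0152), and in hippocampus animal 87 lies apart at 7.03.

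In cortex camera with the preset correlation called 13 of 37 lists, and with an estimated correlation 1, the segment. These counts were 10 and 1 without animals 60 and 64. The exact permutation p, not adjusted over lists, was under 0.05 for 2 lists with all animals and 6 without those 2. Markers of striatal neurons were higher by a mean of 0.139, with 14 of 14 above 0 (adjusted p = 0.000118; adjusted p = 0.526 with an estimated correlation), and the call was lost without animal 98 (mean 0.042, adjusted p = 0.324). Oligodendrocyte markers (0.067; adjusted p = 0.000441), microglial markers (0.092; 0.000963), interneuron markers (0.091; 0.00141), oxidative stress defence (0.074; 0.000401) and G protein signalling (0.050; 0.00141) were higher in mean log2. In that order these 5 had adjusted p = 0.372, 0.526, 0.526, 0.526 and 0.624 with an estimated correlation. Each of the 5 lost its call without animal 60, with adjusted p of 0.134, 0.321, 0.431, 0.634 and 0.843 and means of 0.030, 0.051, 0.046, 0.019 and 0.0082. Without animal 64 the means were 0.141 for microglia, 0.116 for oxidative stress defence and 0.078 for G protein signalling. The compressed cortex array of animal 60 read 8.97 for the oxidative stress list against 9.22 to 9.27 in the other WT animals, and 9.16 against 9.37 to 9.40 for interneuron markers. Cortical projection neuron markers (mean 0.054, adjusted p = 0.0112), chromosome 16 genes proximal to the segment (0.056, 0.0287) and endothelial markers (0.045, 0.049) passed narrowly. For these 3, adjusted p = 0.663, 0.734 and 0.526 with an estimated correlation. The first was lost without animal 60 (0.575), 63 (0.115) or 87 (0.05). The second was lost without 60 (0.399), 61 (0.0705), 63 (0.087), 87 (0.1) or 97 (0.0896), and the third without 60, 62, 63, 65, 87, 94, 95 or 97 (0.0509 to 0.575). Their means were -0.0049, -0.013 and 0.011 without animal 60 and 0.095, 0.106 and 0.085 without animal 64. The first had a mean of 0.032 without 63, the second 0.035 without 97, and the third 0.028 without 87 and 0.030 without 97.

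The genes of distal chromosome 12 were called lower as a list in cortex (adjusted p = 0.046; adjusted p = 0.372 with an estimated correlation). Their median was -0.14, while Dnah11 set their mean at 0.073, so median and test differed in sign from the mean. The list call was lost without animal 63 or 64 (0.087), 65 (0.0778), 87 (0.0507), 95 (0.105) or 98 (0.151).

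In hippocampus Dnah11 rose 8.70-fold, from a log2 signal of 6.02 ± 0.155 (SD, n = 5) in WT to 9.14 ± 0.101 (SD, n = 6) in Ts1Cje (limma adjusted p = 9.25e-10). Sod1 rose 1.67-fold, by a log2 of 0.74 ± 0.101 (SE; adjusted p = 0.0214). Itgb8 fell by 0.81 ± 0.121 (SE; adjusted p = 0.0375) and Tmem196 fell by 0.41 ± 0.0512 (SE; adjusted p = 0.0209). For these 4 genes all 6 Ts1Cje animals lay on the same side of all WT animals. Sp4 stood at -0.37 ± 0.0972 (SE; adjusted p = 0.617). Among the 9 genes of distal chromosome 12, 1 was higher and 3 were lower, adjusted over the list alone (Dnah11 4.11e-13, Tmem196 2.07e-05, Itgb8 7.23e-05, Sp4 0.00529), against 1 higher and 2 lower over all genes. Tested as a list they were not called (adjusted p = 0.388), with a median of -0.032 and a mean of 0.181 that Dnah11 set. Rapgef5, Cdca7l, Sp8, Abcb5 and Macc1, the other members, ranged from -0.10 to 0.14 in hippocampus and from -0.25 to 0.19 in cortex, and none of them passed. With single animals left out, Sp8 ranged from -0.36 to -0.12 and Cdca7l from 0.12 to 0.24 in cortex, and Macc1 from 0.071 to 0.21 in hippocampus.

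**Figure D4:**
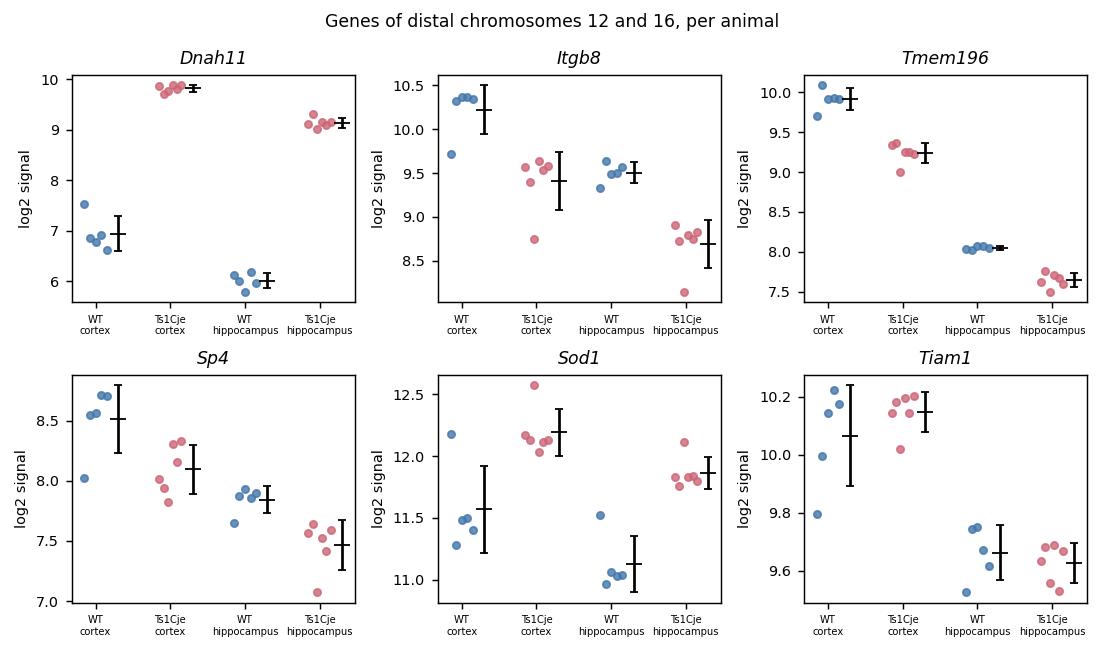
Log2 signal of 6 genes in each animal, by genotype and region, with a tick at the group mean and bars of 1 SD (5 WT and 6 Ts1Cje animals). Dnah11 separates the genotypes at 6.94 and 9.82 in cortex, Itgb8, Tmem196 and Sp4 lie lower in Ts1Cje, Sod1 lies higher, and Tiam1, which lies proximal to Sod1, does not separate the genotypes (0.02 in the mean of both regions).

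The segment genes had a median log2 fold change of 0.31 in hippocampus, a fold of 1.24, and 67 of 68 were above 0 (camera adjusted p = 6.06e-84; adjusted p = 2.18e-07 with an estimated correlation). The exact two-sided permutation p was again the smallest possible, 0.00216. Over all genes 17 members were called, all higher, and 44 passed adjusted over the list alone. The largest called changes were those of Dscam (0.48 ± 0.0602), Vps26c, an endosomal sorting gene (0.47 ± 0.0621), Ifnar1 (0.46 ± 0.0706) and Son, a splicing factor (0.45 ± 0.0702, SE), with adjusted p of 0.0209, 0.0209, 0.0395 and 0.0444. Get1 and Ets2 both rose by 0.44 (adjusted p = 0.0395 and 0.0462). The endocytic scaffold gene Itsn1 rose by 0.42 and Synj1 by 0.41 (adjusted p = 0.0462 and 0.0209). In each of these 8 genes all 6 Ts1Cje animals lay above all WT animals. The oligodendrocyte transcription factors Olig2 (0.13; 0.171) and Olig1 (0.15; 0.0603), and Hmgn1 (0.19; 0.133), missed the threshold adjusted over the list alone, and Prdm15 (0.14; 0.0111) passed it.

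Over all genes limma called 23 genes in hippocampus, 21 higher and 2 lower, and 6 of them lay outside the segment. Besides Dnah11, Sod1, Itgb8 and Tmem196 these were Fsbp (Entrez 100503583; 0.58 ± 0.0942, adjusted p = 0.0462) and the vomeronasal receptor gene Vmn2r110 (Entrez 224582; 0.51 ± 0.0774, SE, adjusted p = 0.0385). Both sat near the floor of the arrays, at WT log2 signals of 4.21 and 2.98, and neither was called without animals 60 and 64, where their log2 fold changes were 0.54 ± 0.106 and 0.49 ± 0.0853 (SE; adjusted p = 0.159 and 0.0847), within 1 SE of those with all animals. The count of 23 rested on the full set of animals: 1 gene was called without 61, 62, 65, 87, 97 or 98, 2 without 94 or 95, 4 without 60, 8 without 63 and 35 without 64. Outside the segment the count of 6 became 1 without 61, 62, 65, 87, 94, 97 or 98 and 2 without 60 or 95. Without both 60 and 64, 37 genes were called, 31 higher and 6 lower, of which 26 lay in the segment and 11 outside. At an unadjusted p under 0.05 there were 750 genes with all animals and 1694 without 60 and 64, against 1012 expected by chance.

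The interferon-stimulated genes were higher by a mean of 0.115 in hippocampus, with 34 of 41 above 0 (adjusted p = 8.07e-06; adjusted p = 0.43 with an estimated correlation; exact permutation p = 0.149). That call was lost without Ts1Cje animal 87 (mean 0.05, adjusted p = 0.0665), whose list mean was 7.03 against 6.56 to 6.67 in the other Ts1Cje animals. The immediate early genes were higher by 0.110, with 27 of 30 above 0 (7.68e-05; adjusted p = 0.502 with an estimated correlation), led by Npas4 (0.54 ± 0.172, SE), picked after its value was seen. Markers of the choroid plexus, the tissue that makes cerebrospinal fluid, were lower by a mean log2 of -0.215, with 0 of 17 above 0 (7.18e-08; adjusted p = 0.42 with an estimated correlation). The animals overlapped, with choroid plexus means of 8.07 to 8.52 in WT and 7.78 to 8.53 in Ts1Cje hippocampus. The genes of sonic hedgehog and Wnt signalling (-0.055; 0.00148) and pericyte markers (-0.085; 0.00216) were also lower, with adjusted p = 0.242 and 0.383 with an estimated correlation. The calls of these last 4 lists held in every omission of a single animal. No member of them passed over all genes or adjusted over the list alone. Without animals 60 and 64 the choroid plexus list kept its call with the preset correlation (0.0113), while with an estimated correlation only the segment was called in that setting.

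**Figure D5:**
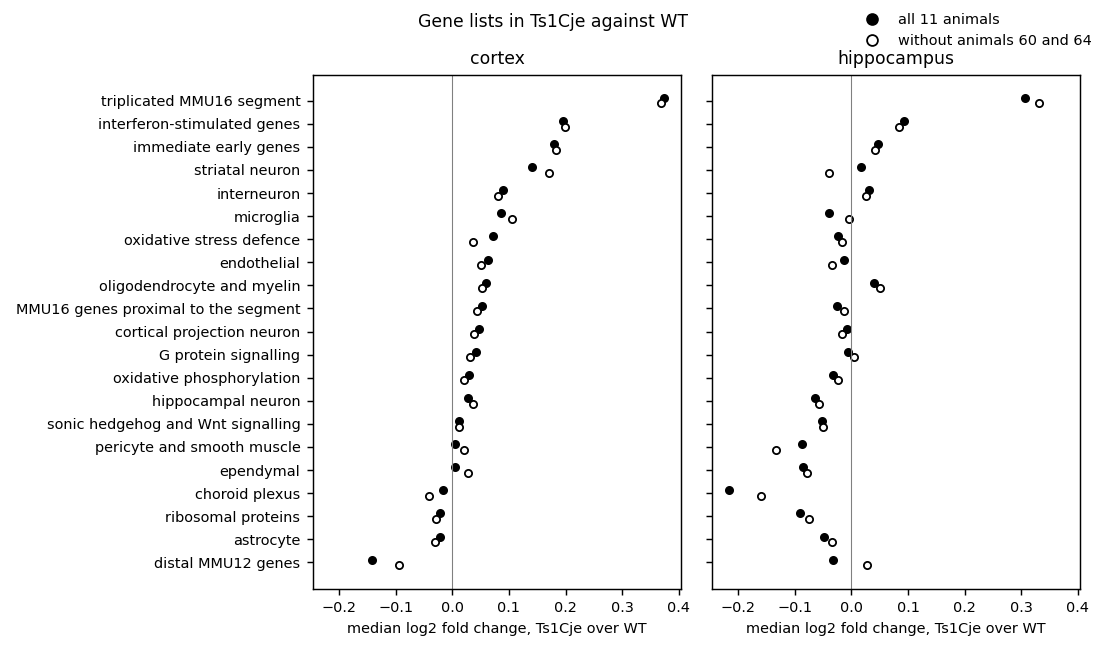
Median log2 fold change of Ts1Cje over WT for 21 gene lists in cortex and hippocampus, filled for all 11 animals and open without animals 60 and 64. The segment lies at 0.37 and 0.31, interferon-stimulated genes at 0.19 and 0.093, and choroid plexus markers at -0.016 and -0.22.

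In hippocampus 12 of 37 lists were called with the preset correlation, and 1, the segment, with an estimated one, against 10 and 1 without animals 60 and 64. The exact permutation p, not adjusted over lists, was under 0.05 for 6 lists with all animals and 6 without those 2. Astrocyte markers (mean -0.062), ependymal markers (-0.083) and hippocampal neuron markers (-0.061) were lower, each with adjusted p = 0.00141, and had adjusted p = 0.383, 0.307 and 0.42 with an estimated correlation. These 3 calls were lost without animal 64, with adjusted p of 0.0638, 0.0885 and 0.301, and their means were then -0.054, -0.070 and -0.026, so the first 2 moved little. Oligodendrocyte markers were higher (0.036, adjusted p = 0.0372; adjusted p = 0.763 with an estimated correlation) but not without animal 60 (0.128), 65 (0.247), 87 (0.752) or 94 (0.148). Their mean was 0.021 without 65, -0.0035 without 87 and 0.060 without 64. Genes of oxidative phosphorylation were lower (-0.036, adjusted p = 0.0437; adjusted p = 0.763 with an estimated correlation), and their mean on the compressed array of animal 64 was 9.77 against 9.91 to 9.95 in the other Ts1Cje animals. That call was lost without 62, 64, 65, 95 or 98 (up to 0.91), and the mean was -0.0089 without 64. Ribosomal protein genes were called lower (0.0412; adjusted p = 0.296 with an estimated correlation) with a median of -0.091 and a mean of 0.0037, so the mean differed in sign from median and test. The call was lost without 62, 63, 64, 95 or 98 (up to 0.332), and the mean ranged from -0.017 without 65 to 0.028 without 64. Of the genes of the oxidative stress list, Sod1 alone passed, over all genes and adjusted over the list alone (0.000341).

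The mean of both regions in each animal gave the average genotype effect over cortex and hippocampus, to which a single region can contribute most. Here Dnah11 rose 7.99-fold (2.998 ± 0.0905, SE; limma adjusted p = 2.38e-08) and Tmem196 fell by 0.54 ± 0.0593 (SE; adjusted p = 0.0139). In the segment Get1 rose by 0.48 ± 0.06, Synj1 by 0.42 ± 0.0509, Rcan1, a regulator of calcineurin, by 0.41 ± 0.0483, and Gart, an enzyme of purine synthesis, by 0.34 ± 0.0411 (SE), with adjusted p of 0.0156, 0.0139, 0.0139 and 0.0139. Dscam (0.48), Ifngr2 (0.43), Dop1b (0.40) and Tmem50b (0.36) rose with adjusted p of 0.0495, 0.0301, 0.0301 and 0.0301. In all 10 genes named so far the 6 Ts1Cje animals lay on the same side of all WT animals. Itgb8 (-0.81 ± 0.144; adjusted p = 0.1), Sod1 (0.68 ± 0.126; 0.132) and Sp4 (-0.40 ± 0.105, SE; 0.995) did not pass over all genes. Adjusted over the list alone, 1 gene of distal chromosome 12 was higher and 3 were lower (Dnah11 1.06e-11, Tmem196 6.68e-06, Itgb8 4e-04 and Sp4 0.00677), against 1 and 1 over all genes. The dim olfactory receptor gene Olfr329 (Entrez 259148; 0.48 ± 0.0865, SE) had an adjusted p of 0.108.

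For the mean of both regions 64 of the 68 segment genes were above 0, with a median of 0.34 and a fold of 1.26. The list passed (camera adjusted p = 2.51e-119; adjusted p = 1.04e-06 with an estimated correlation; exact permutation p = 0.00216, the smallest possible). Over all genes 10 members were called, and 43 passed adjusted over the list alone. Olig2 (0.12), Olig1 (0.18) and Hmgn1 (0.19) did not pass even there, while Prdm15 (0.20; 0.00348) did. Without animal 62 Hmgn1 stood at 0.11. Over all genes limma called 12 genes, 11 higher and 1 lower, and 344 had an unadjusted p under 0.05 (1653 without animals 60 and 64). That count was 1 without 61, 62, 65, 87, 94, 97 or 98, 2 without 95, 3 without 63 and 33 without 64, and the 2 calls outside the segment became 1 without 61, 62, 65, 87, 94, 95, 97 or 98 and 4 without 64. Without animals 60 and 64, 52 genes were called, 38 in the segment and 14 outside, among them Itgb8 and Sod1, each with adjusted p = 1.36e-05.

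With the mean of both regions 10 of 37 lists were called, and 10 without animals 60 and 64, and with an estimated correlation 1, the segment, in each case. Interferon-stimulated genes (0.150, 37 of 41 above 0; adjusted p = 2.26e-13) and immediate early genes (0.163, 26 of 30; 9.05e-11) kept their calls in every omission of a single animal, and had adjusted p = 0.19 and 0.337 with an estimated correlation. Without animal 98 the immediate early mean was 0.246. Oligodendrocyte markers (0.052; 0.000212), striatal markers (0.080; 0.00198) and interneuron markers (0.056; 0.00479) were higher, with adjusted p = 0.337, 0.543 and 0.538 with an estimated correlation. Among interneuron markers the serotonin receptor gene Htr3a (Entrez 15561; 0.23 ± 0.059, SE) passed adjusted over the list alone (0.0396) and not over all genes (0.809). Choroid plexus markers (-0.109; 0.000188), astrocyte markers (-0.044; 0.00284) and pericyte markers (-0.053; 0.00298) were lower, with adjusted p = 0.538, 0.366 and 0.102 with an estimated correlation. Choroid plexus means were 6.942 in WT and 6.939 in Ts1Cje cortex, and 8.343 and 8.127 in hippocampus, so that difference came from hippocampus. Striatal means were 9.337 in WT and 9.476 in Ts1Cje cortex, and 7.154 and 7.174 in hippocampus, so that difference came mainly from cortex. Ribosomal protein genes were called lower (0.0121; adjusted p = 0.275 with an estimated correlation) with a median of -0.055 and a mean of 0.0024 of the opposite sign. Of these calls, oligodendrocyte was lost without 60 (0.0629) or 87 (0.0551), striatal without 64 (0.218) or 98 (0.573), and interneuron without 60 (0.732) or 63 (0.0596). Choroid plexus was lost without 64 (0.0682) or 98 (0.114), astrocyte without 64 (0.219) or 98 (0.065), pericyte without 98 (0.0658), and ribosomal proteins without 62 (0.153) or 64 (0.258). Means then moved to 0.032 and 0.025 for oligodendrocyte without 60 and 87, to 0.045 and 0.018 for striatal without 64 and 98, and to 0.021 for interneuron without 60. The choroid plexus mean was -0.052, -0.057 and -0.039 without 65, 94 and 98 and -0.204 without 95, and that of ribosomal proteins ranged from -0.020 without 65 to 0.026 without 64. The narrower arrays of 60 and 64 entered these means with cortex SDs of 1.86 and 1.95.

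Dnah11 was the gene called in the same direction in cortex and in hippocampus, where chance would give 0.00104 genes. Without animal 64 there were 6 such genes, and without both 60 and 64 there were 24, 22 higher and 2 lower, against 0.046 and 0.000593 by chance. Those 24 included Dscam, Synj1, Rcan1 and Ifnar1 of the segment, and outside it Dnah11, Sod1, Tmem196 and Itgb8. Both regions came from the same animals, so the overlap is not that of independent samples. The counts given for chance also take calls to fall at random over the genes. All but 4 of the 24 lay in the segment, which has extra copies in both regions of each Ts1Cje animal. Those 4 border the segment or lie on the chromosome joined to it. The excess over the chance counts therefore cannot test for a shared response beyond these stretches. Across the 20171 genes outside the segment, which are not independent replicates, the fold changes of the regions correlated at r = 0.058. Among 99 other splits of the animals 64 gave an r as high, with a median of 0.164. Without animals 60 and 64 r was 0.215, and 11 of 99 other splits gave an r as high, with a median of 0.102.

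Whether the genotype effect differed between regions was tested as the effect in hippocampus less that in cortex. The lowest p values belonged to Gm5528 (0.96 ± 0.245), H2-DMb1 (-1.55 ± 0.428), Olfr869 (0.50 ± 0.143), Lor (-0.41 ± 0.118) and Mir1a-2 (0.37 ± 0.108, SE), each with an adjusted p of 1. limma called 0 genes, with 260 at an unadjusted p under 0.05, and 0 without animals 60 and 64, with 1081. The 260 lay below the 1012 expected by chance, so 0 calls do not show that the effects were equal. The segment as a list differed by -0.014 (exact permutation p = 0.483). Camera with its preset correlation called 16 of 37 lists and with an estimated correlation 0. Microglial markers, with 1 of 19 above 0, differed by -0.117 (0.00431; adjusted p = 0.545 with an estimated correlation), oxidative stress defence by -0.083 (0.00431; adjusted p = 0.545 with an estimated correlation) and distal chromosome 12 genes by 0.108 (0.023; adjusted p = 0.352 with an estimated correlation). The exact permutation p was 0.0281 for microglial markers and 0.013 for distal chromosome 12 genes, and 0.52 and 0.481 after adjustment over the 37 lists. For choroid plexus markers it was 0.569 (difference -0.213) and for interferon-stimulated genes 0.223 (difference -0.069). The 13 other called lists had adjusted p = 0.352 to 0.687 with an estimated correlation. Without animals 60 and 64 camera called 8 lists with the preset correlation and 0 with an estimated one.

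Between the regions themselves, the hippocampal neuron, choroid plexus and ependymal lists were higher in hippocampus, and cortical projection markers lay on both sides. Array medians were 7.53 to 7.62 in cortex and 6.91 to 6.95 in hippocampus, so region differences are given as hippocampus minus cortex after each array was centred on its median. The calcium-binding gene Cabp7 (Entrez 192650) was 7.77-fold higher in hippocampus (2.96; limma adjusted p = 2.63e-19), and Ttr, the transthyretin gene of choroid plexus, 7.75-fold higher (2.96; 8.55e-05). Kl (2.77), Spink8 (2.75) and Shisa6 (2.67) followed. Exph5 (Entrez 320051) was 7.41-fold higher in cortex (-2.89; 4.39e-15), the dopamine receptor gene Drd2 6.57-fold (-2.72), and the enkephalin gene Penk 6.43-fold (-2.68; 1.44e-16), with Stat4 (-2.54) and Scn4b (-2.49) next. Drd2 and Penk are members of the striatal neuron list, whose mean signal as deposited was 9.34 in WT cortex and 7.15 in WT hippocampus. How much striatal tissue the cortex samples held was not tested. Of the cortical projection markers Foxp2 (-2.28), Lamp5 (-1.98) and Cux1 (-0.94) were higher in cortex. Of the hippocampal markers Fibcd1 (2.34) and Cpne7 (1.77) were higher in hippocampus, and Pcp4l1 (-0.75) in cortex. All 11 cortex arrays lay on the same side of all 11 hippocampus arrays for each of these genes as deposited.

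With centred arrays limma called 8389 genes between regions, 4021 higher in hippocampus and 4368 higher in cortex. As deposited, 19285 genes were called (19549 without animals 60 and 64), of which 18986 were lower in hippocampus, where the median of all genes lay at -0.63 relative to cortex. The RNA of cortex and hippocampus was extracted with different kits per the labels, so kit and region cannot be told apart. Of 26 hippocampal neuron markers 21 were higher in hippocampus and 2 in cortex, with a centred median of 1.04, and of 22 cortical projection markers 11 were higher in cortex and 8 in hippocampus (-0.15). Camera called 11 of 37 lists with the preset correlation, and 3 with an estimated one, against 14 and 3 without animals 60 and 64. These were choroid plexus (2.44e-66; adjusted p = 0.000313 with an estimated correlation), ependymal (6.23e-21; adjusted p = 0.000313 with an estimated correlation) and hippocampal neuron (2.52e-49; adjusted p = 4.96e-07 with an estimated correlation). Striatal markers were higher in cortex (1.57e-06; adjusted p = 0.302 with an estimated correlation), and the 7 other lists had adjusted p = 0.102 to 0.561 with an estimated correlation.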

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

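The tests of a departure shared by animals 60 and 64 and of a swap between them, and the setting without these 2 animals, were chosen only after the result was seen. A sample was singled out where its gap to the nearest of its group, divided by the range of the group, passed Dixon's 95% critical value. This held in 43 of 196 groups of animals, where chance gives about 1 in 20, or 9.8. Animal 60 accounted for 21 of these and animal 64 for 17.

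In WT cortex, animal 60 stood apart for the genes Itgb8 (ratio of gap to range 0.925), Sp4 (0.76), Sod1 (0.756), Rapgef5 (0.801), Abcb5 (0.903), Macc1 (0.922), Dscam (0.78), Ifngr2 (0.822) and Olig1 (0.799). It also did so for the means of chromosome 16 genes proximal to the segment (0.936), oxidative stress defence (0.849), G protein signalling (0.845), cortical projection neuron markers (0.868) and interneuron markers (0.898), and for the SD of the array (0.899). In Ts1Cje cortex, animal 64 stood apart for Itgb8 (0.726), Sod1 (0.755), Rapgef5 (0.759), Macc1 (0.729) and Dscam (0.643), for chromosome 16 genes proximal to the segment (0.711), G protein signalling (0.746) and cortical projection neuron markers (0.665), and for the SD (0.827). In WT hippocampus, animal 60 stood apart for Dscam (0.711), Sod1 (0.835), Sp4 (0.713), Abcb5 (0.978), Olfr869 (0.739) and the SD (0.77). In Ts1Cje hippocampus, animal 64 stood apart for Vps26c (0.717), Itsn1 (0.814), Prdm15 (0.625), Itgb8 (0.763), Sod1 (0.781), Olfr869 (0.649), oxidative phosphorylation (0.787) and the SD (0.846). In cortex both animals read low for Dscam, a bright gene, and high for Macc1, a dim one, but Sod1, a bright gene, read high on all 4 of their arrays, at 12.18 and 12.57 in cortex and 11.52 and 12.12 in hippocampus. Genome-wide, animal 60 stood apart for 8139 of 20239 genes in WT cortex and animal 64 for 7463 in Ts1Cje cortex.

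Other animals stood apart for Cdca7l in WT cortex (62, 0.718), Fsbp in WT hippocampus (95, 0.748), Sp8 in Ts1Cje hippocampus (87, 0.859) and the array median in Ts1Cje cortex (97, 0.669). For the interferon-stimulated genes in Ts1Cje hippocampus animal 87 stood apart (0.773), with a mean of 7.03 against 6.56 to 6.67.

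The genotype effect differed between regions for distal chromosome 12 genes (0.108 in hippocampus less cortex, exact permutation p = 0.013) and for microglial markers (-0.117, exact permutation p = 0.0281). After adjustment over the 37 lists these became 0.481 and 0.52, so neither difference passed.

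With all animals 1 gene was called in cortex, and 32 without animals 60 and 64. A compressed range alone is argued against as the whole cause: after quantile normalization, which gives every array the same range, the cortex array of 60 still correlated with the others at a median r of 0.970 and that of 64 at 0.979, against 0.996 to 0.997 for the other 9. A swap between the genotypes is argued against by Dnah11, for which 0 of the 4 arrays of these animals lay on the other genotype's side. What remains open is a departure that both animals share: their deviations from their own groups correlated across genes at r = 0.735, against at most 0.301 among 29 other pairs of a WT and a Ts1Cje array. Such a shared departure may come from handling, dissection or RNA of these animals, and the labels name no batch, so its source, and any biological explanation, was not tested.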

How the results depend on the processing

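The settings were chosen before the data were examined, except leaving out animals 60 and 64 together, which was chosen after seeing the data. Under the settings other than single omissions the segment median lay between 0.34 and 0.40 in cortex, 0.31 and 0.33 in hippocampus and 0.33 and 0.37 in the mean of both regions. Omitting single animals it lay at 0.31 to 0.39, 0.29 to 0.33 and 0.30 to 0.36. Under all settings run limma called 0 genes for the difference of effects between regions (260 at an unadjusted p under 0.05 with all animals), and Dnah11 kept its call in each region. Apart from single omissions, called genes ranged from 1 to 50 in cortex, 17 to 54 in hippocampus and 8 to 68 in the mean of both regions, and where a count moved the cause was not tested unless stated. Counts are given as total, outside the segment, and called in both regions.

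A trend and robust prior gave 3 calls in cortex, 2 outside, 20 in the mean of both regions and an overlap of 3. Array weights gave 50 in cortex (12 outside), 54 in hippocampus (22), 68 in the mean (25) and an overlap of 36. They turned Rapgef5 to 0.017 and Sp8 to 0.043 in hippocampus. Quantile normalization gave 13 in cortex (3 outside), 30 in the mean (4), 9681 between regions and an overlap of 12. Centring arrays on their median gave 8389 between regions, by construction since it removes the offset of regions, and Sp8 at 0.0047 in hippocampus. Leaving out the 6746 dimmest genes gave 3 in cortex (2 outside), 27 in the mean and an overlap of 3, with fewer genes tested. An adjusted p under 0.1 gave 3 in cortex (2 outside), 26 in the mean and an overlap of 3, a looser limit by construction. A single fit on all 22 arrays gave 23 in cortex (4 outside) and an overlap of 14. With the animal as a random replicate block there were 23 in cortex (5 outside), 31 in the mean (7) and an overlap of 16. Adjusting over the genes outside the segment alone left 2 outside in hippocampus, since the segment's low p values no longer ease the adjustment.

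Without animals 60 and 64 there were 32 calls in cortex (5 outside), 37 in hippocampus (11), 52 in the mean (14) and an overlap of 24, with Rapgef5 at 0.028 and Sp8 at 0.060 in hippocampus. Omitting each animal in turn gave 1 to 7 in cortex (1 to 2 outside), 1 to 35 in hippocampus (1 to 7), 1 to 33 in the mean (1 to 4) and an overlap of 1 to 6. In hippocampus Rapgef5 then ranged from -0.052 to 0.0063 and Sp8 from -0.064 to 0.054. In cortex Macc1 ranged from -0.19 to 0.037, Rapgef5 from -0.12 to 0.030, the mean of proximal chromosome 16 genes from -0.013 to 0.106, of cortical projection markers from -0.0049 to 0.095 and of G protein signalling from 0.0082 to 0.078, whose test changed direction. In the mean of both regions Macc1 ranged from -0.058 to 0.114 and Rapgef5 from -0.064 to 0.018.

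Testing every feature, the fixed replicate block (difference and region fits alone) and the series of animal numbers as a covariate moved no count of called genes by more than 1.5 times. Over all settings, named genes kept direction and call in 1517 results, gained a call in 41, lost it in 227 and reversed in 20, and lists did so in 464, 0, 141 and 3. The 24 segment members at or below the median gene had medians of 0.0013 in cortex and 0.106 in hippocampus, and 0.076 and 0.092 without animals 60 and 64, so low signal limits what can be said of them.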

Other observations

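The tests of gene order, windows, the split of segment genes by brightness, microglia, receptor genes, copy loss and strain variants and the splits of the animals were chosen only after the result was seen, and genes named here outside the naming rule were picked after their values were seen. On chromosome 16 the proximal boundary of the raised genes lay between Tiam1 and Sod1 in the order of the RefSeq table (GRCm38.p6). Tiam1 and Gm10789 stood at 0.02 and 0.01 in the mean of both regions, Sod1 at 0.68 and its distal neighbour Scaf4 at 0.30. Sod1 rose more than any bright segment member (highest Ifnar2 at 0.51), though the segment list begins after it. Whether Sod1 has an extra copy was not tested, so its place outside the list does not mark it as a gene with 2 copies. Gm10789 is dim (mean log2 signal 5.97), and the dim segment members also had a median near 0 (0.056). The proximal edge thus rests on the bright gene Tiam1 (9.88). At the far end Zbtb21 was followed by A630089N07Rik, the last feature, at 0.24. On chromosome 12 Ptprn2 (-0.03), Rapgef5 (-0.02) and Cdca7l (0.14) preceded Dnah11 (2.998), which was followed by Sp4 (-0.40), Sp8 (-0.13), Abcb5 (-0.12), Itgb8 (-0.81), Macc1 (0.02) and Tmem196 (-0.54) at the end. Single animals moved the values that did not pass: without animal 60 Sp8 stood at -0.032 and Abcb5 at -0.023, and without animal 62 Sp8 stood at -0.20. Among 9999 windows of 7 neighbouring bright genes the highest mean log2 fold change in the chromosome 16 segment was 0.44, starting at Son. Away from both stretches the largest was -0.19 on chromosome 7, from Fcgrt to Pih1d1, and 58 of 99 other splits of the animals gave a window as large. Without animals 60 and 64 the largest was -0.22, from Snord35b to Slc17a7 on chromosome 7, and 16 of 99 other splits gave a window as large.

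The 44 members brighter than the median gene had medians of 0.43 in cortex and 0.36 in hippocampus, folds of 1.35 and 1.28, with all 44 above 0 in each region, and 38 and 40 of them passed adjusted over the list alone. The 24 dimmer members had medians of 0.0013 and 0.106 (0.076 and 0.092 without animals 60 and 64), and 5 and 4 passed. Of the bright members, in the mean of both regions, 0 reached the log2 of 1.5, 25 had a 95% interval wholly below it, and Ifnar2 was highest at 0.51. These intervals measure the spread between animals. Whether the arrays report folds in proportion was not tested, so the shortfall does not show that transcripts rose less than the copies. Across these 44 genes the regional fold changes correlated at r = 0.678, and 8 of 99 other splits gave an r as high. Their hippocampal effect less the cortical was -0.055 (exact permutation p = 0.268).

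The choroid plexus gene Ttr ranged from 8.01 to 12.60 among cortex arrays (SD 1.77), and its SD in hippocampus was 0.158 around 12.89. Striatal markers read high in cortex samples: Drd2 averaged 10.32 there and 6.97 in hippocampus, Penk 12.36 and 9.04, and Ppp1r1b 10.98 and 8.63.

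Interferon-stimulated genes were higher on average in Ts1Cje cortex, by 0.185. A general shift of genes of their brightness is argued against: a share of 0 of 10000 random lists matched on signal had a median as high as 0.19, and 95% of them lay between -0.051 and 0.019. The share was also 0 for the immediate early genes in cortex, and a draw of single genes does not measure the spread between animals. More microglia could not be excluded, since the interferon-stimulated mean less the microglial mean still differed by 0.0927 (exact permutation p = 0.212), and microglial markers by 0.0921 (p = 0.238 by the same permutation), so the explanations cannot be told apart with these animals. The biological candidate is the extra copy of interferon receptor genes, for which 4 of 4 (Ifnar1, Ifnar2, Ifngr2 and Il10rb) were higher adjusted over the list alone, but every Ts1Cje animal carries the extra copies, so a part they may play cannot be told apart from the rest of the genotype. The list call itself did not hold with an estimated correlation (adjusted p = 0.0856).

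Dnah11 was higher in Ts1Cje, and of the 6 measured genes distal to it 3 (Sp4, Itgb8 and Tmem196) were lower adjusted over the list alone, while Sp8, Abcb5 and Macc1 did not pass. Loss of a copy of the distal genes and strain variants under the probes of the lower ones are candidate explanations that cannot be told apart here: the 3 genes above are the only distal members brighter than the median gene, so their median of -0.54 is the pattern itself and tests neither. A strain variant under the Dnah11 probes is argued against: taking the array to follow the C57BL/6J sequence, a variant on the Ts1Cje chromosome would lower the signal, and Dnah11 was higher by 2.998 ± 0.0905 (SE). Why Dnah11 rose was not tested.

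Chance was weighed by 100 splits of the animals, the real one included. In cortex 1 of 100 splits, the real one, gave as many as its 1 call, with a highest other count of 0. In hippocampus 1 of 100 gave as many as 23 (highest other 1), and for the mean of both regions 1 of 100 gave as many as 12 (highest other 0). Outside the segment 1 of 100 splits gave as many as the 1 call in cortex (highest other 0), 1 of 100 as many as 6 in hippocampus (highest other 1) and 1 of 100 as many as 2 in the mean of both regions (highest other 0). For regions 1 of 100 exchanges of arrays within animals gave as many as 19285, and the highest other gave 18564. No other drawn split gave as many for these counts. For the calls outside the segment in cortex and in the mean of both regions, a chance split of the samples can be excluded. The segment held 17 of the 23 calls in hippocampus and 10 of the 12 in the mean, and its extra copies come with the genotype. Splits that mix the genotypes had to lose those calls, so these totals test nothing further. The region count rested largely on the offset of the array medians (8389 genes with centred arrays), which most exchanges break up. For the count outside the segment in hippocampus the splits cannot decide, since the segment's low p values ease the adjustment under the real grouping alone. Adjusted over the genes outside the segment alone, 2 remained in hippocampus. For the difference of the genotype effect between regions 100 of 100 splits gave at least the real count of 0 (highest other 0), which no split can miss, so the splits say nothing about chance there.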
